A study of Mus musculus with 12 samples.

How the data were processed

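RNA was measured by sequencing in 12 libraries from mouse left ventricle, 3 in each of 4 groups. The groups cross genotype, wild type (WT) or Alox5 knockout (Alox5ko), with treatment, TAC or NS. TAC is transverse aortic constriction, an operation that narrows the aorta and overloads the left ventricle. The labels do not spell out NS, which is used here as the name of the group without TAC. Per the labels, total RNA was extracted with TRIzol, polyadenylated RNA was taken on oligo(dT) beads, and directional libraries were sequenced as 150-bp read pairs on a NovaSeq 6000.

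The submitters' notes name HISAT2 for alignment, DESeq2 for analysis, and the builds GRCh38 and mm10, with no versions. The counting program, the annotation release and the strand setting are not given. The authors deposited a table of raw counts per gene symbol for 49492 rows, of which 28070 have a count in at least 1 library. The authors also deposited RPKM values, which are counts scaled by gene length and library total. All 336840 RPKM values were recomputed from the counts and the deposited gene length and were equal within 0.1%. Both tables also carry the deposited gene length in bases. Of the symbols, 47209 lie on the same chromosome in GENCODE release M21 (GRCm38, which is mm10), and 42938 of these (90.95%) have the same start and end, so positions are given in that build. In 26 rows the symbol had been turned into a date, and these genes are not named.

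Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 15542 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries with robust estimation. Each of 4 comparisons and the interaction (the TAC response of Alox5ko minus that of WT) was tested with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in the comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p for a gene comes from this edgeR test unless another tool is named. Levels of genes are given as CPM, counts scaled to a common library size with the TMM factors, with the standard deviation (SD) between 3 libraries. Summed levels of a list are CPM scaled by the library total alone, without the TMM factors. Fold changes are on the log2 scale with their standard error (SE).

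Library totals ran from 20889431 to 27311196 counts, TMM factors from 0.945 to 1.035, and the common biological coefficient of variation was 0.107. The labels do not say that each library came from another animal, so the p-values measure the spread between these samples. Between libraries of 1 group the chi-square per gene was 5.39 to 31.8, so none was a copy of another. An exact two-sided permutation test of 3 against 3 libraries cannot go below 0.1, so single genes were tested only by the model. With 3 against 3, chance separates the groups of a gene without overlap for 10% of genes.

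The genes named were set by a rule written before the data were examined. The first part takes Alox5, Runx2 and Egr1 in every comparison. The second takes the 10 highest and 10 lowest fold changes among called genes in WT_TAC vs WT_NS and Alox5ko_TAC vs WT_TAC, and 5 and 5 elsewhere, leaving out predicted gene models, genes under a mean log2 CPM of 1 and genes whose groups overlap. The third takes up to 4 members of each list with the smallest adjusted p, and the fourth the 5 smallest p-values where fewer than 5 genes are called. Genes named outside it are said to be so.

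A set of 34 gene lists, 18 pathways or gene groups and 16 sets of cell type markers, was fixed at the same time. The gene groups were the fetal and hypertrophic program, extracellular matrix and fibrosis, the arachidonic acid and leukotriene pathway, the Runx family and textbook Runx2 targets, immediate early genes, fatty acid oxidation, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, glycolysis, sarcomere, calcium handling and ion channels, TGF-beta and BMP signalling, chemokines and cytokines, interferon response, cell cycle, unfolded protein and heat shock response, circadian clock, and sex-linked genes. The marker sets were those of cardiomyocytes, fibroblasts, activated fibroblasts, endothelium, smooth muscle and pericytes, macrophages, neutrophils, T cells, B cells, atrial myocytes, adipocytes, erythroid cells, epicardium and mesothelium, skeletal muscle, Schwann cells and neurons, and lung and airway epithelium. Each list with at least 3 tested genes, 29 in all, was tested by camera with its preset correlation of 0.01, adjusted over the 29 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way without setting it against other genes, were run as alternatives.

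The fit was tested on simulated data in which 200 genes were changed by known folds. It called 65.7% to 68.7% of genes changed 2-fold in the comparisons of 2 groups and 64.2% in the interaction, and 10.4% of genes changed 1.5-fold in the interaction. Of all its calls, 5.63% to 8.85% were false. The simulated genes varied independently of one another and no simulated library was made to stand apart, so these shares may be better than in the real data.

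The alternatives were RLE scaling, no filter, a filter of 1 CPM in 3 libraries, a term for the replicate number, no robust estimation, a fit of only the 6 libraries compared, DESeq2 1.42.0, limma on log2(RPKM + 1) and on log2(RPKM + 0.1), a fold of at least 2, and leaving out each library in turn. Alternatives chosen after seeing the data were a covariate for atrial RNA, a fit of 10 libraries, a fit of nuclear genes alone, and a fit with 1 gene kept per group of overlapping genes of the Hist2 cluster. The fit of nuclear genes alone also left out some nuclear gene models that resemble mitochondrial genes, which held 5.71% to 7.65% of counts per library. No library and no column of values was left out of the main test.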

Results

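Gene expression was measured in 12 left ventricle libraries, 3 each of WT_NS, WT_TAC, Alox5ko_NS and Alox5ko_TAC. Totals were 21328937 to 22372490 counts in WT_NS, 20889431 to 23196760 in WT_TAC, 23792567 to 27311196 in Alox5ko_NS and 21185989 to 23820523 in Alox5ko_TAC. The series title names arachidonate 5-lipoxygenase, the product of Alox5, together with Runx2 and ventricular remodeling. The design text speaks of cardiac deficiency, while the sample labels give only the genotype.

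Alox5, the enzyme that starts leukotriene synthesis (chromosome 6, 116410077 to 116461178, ENSMUSG00000025701.12), was low in all 6 knockout libraries. Its level was 13.0, 10.5 and 13.9 CPM in WT_NS and 13.4, 9.56 and 12.2 CPM in WT_TAC. It was 1.46, 1.12 and 0.934 CPM in Alox5ko_NS and 1.36, 1.14 and 1.10 CPM in Alox5ko_TAC. Alox5 fell by 3.40 on the log2 scale without TAC (SE 0.185, adjusted p = 1.8e-09) and by 3.28 with TAC (SE 0.189, adjusted p = 5.37e-09). TAC itself gave Alox5 values of -0.09 in WT (SE 0.145, adjusted p = 0.878) and 0.03 in Alox5ko (SE 0.243, adjusted p = 0.975).

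The first comparison asks how the wild-type left ventricle responds to TAC. In WT_TAC against WT_NS, 119 of 15542 genes changed; 74 rose and 45 fell, 33 of them by at least 2-fold. Nlrc3, a brake on innate immune signalling (chromosome 16, 3945007 to 3976632), rose by 2.11 (SE 0.28, adjusted p = 0.00287), from 0.861 ± 0.276 to 3.72 ± 0.992 CPM (SD, n = 3). Pi16, a secreted protein of fibroblasts, rose from 26.3 ± 2.72 to 74.25 ± 19.98 CPM (SD, n = 3), the complement gene C4b rose by 1.49, and the tendon transcription factor Scx rose by 1.41. Acot1, an acyl-CoA thioesterase, fell from 8.63 ± 1.26 to 4.13 ± 0.987 CPM (SD, n = 3), and the water channel gene Aqp4 fell from 3.78 ± 0.496 to 1.65 ± 0.47 CPM (SD, n = 3). The other rises named by the rule were Slc17a7, Dact1, Cpxm2, Nab2, Cdh4 and Cnksr1, from 1.46 for Slc17a7 to 1.25 for Cnksr1. The other falls were Colq, Tmem82, Slc37a2, Celsr3, Sdc4, AI507597, Siah2 and Ifit1, from -1.22 for Colq to -0.86 for Ifit1. AI507597 lies within the span of Tmem82 on the opposite strand, and the strand setting of the counting is not given, so these 2 falls are not taken as separate. No library of 1 group overlapped the other for any of the 119 genes, but the genes were called on these same values, so this is no separate support.

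All 18 tested fetal and hypertrophic genes had a positive value in WT_TAC against WT_NS, with a median of 0.64 (adjusted p = 7.98e-15 by camera with its preset correlation). That call was lost at an adjusted p = 0.355 with an estimated correlation. Only the intermediate filament gene Des passed over all genes, at 0.56 (SE 0.114, adjusted p = 0.0343), and 10 passed adjusted over the list alone. The natriuretic peptide gene Nppa had 216 ± 62.0 CPM in WT_NS and 874 ± 327 CPM in WT_TAC (SD, n = 3), a value of 2.02 (SE 0.538, adjusted p = 0.165). Of 45 extracellular matrix genes, 42 had a positive value, with a median of 0.51 (adjusted p = 0.541 with an estimated correlation); 44 did not pass over all genes, and 8 passed adjusted over the list alone. The summed level of the matrix genes was 4948, 2681 and 3058 CPM in WT_TAC 1, 2 and 3 against 3127, 3268 and 2833 CPM in WT_NS, so only WT_TAC 1 lay above WT_NS. Spp1, osteopontin, had 52, 16 and 15 counts against 4, 6 and 4 and did not pass (adjusted p = 0.0788), nor did Fn1 at 0.64 (adjusted p = 0.12) and Cilp at 2.36 (adjusted p = 0.134). Fibroblast markers had a median of 0.27 with Pi16 called and 2 adjusted over the list alone; activated fibroblast markers had a median of 1.02, none called and 2 adjusted over the list alone. The summed level of the activated fibroblast markers was 371, 117 and 146 CPM in WT_TAC 1, 2 and 3, and at most 83.5 CPM in WT_NS.

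Fatty acid oxidation genes had a median of -0.18 in WT_TAC against WT_NS, and the call of the list by camera was lost at an adjusted p = 0.355 with an estimated correlation. Acot1, the thiolase gene Acaa2 (-0.36) and the isomerase gene Ech1 (-0.40) fell, 31 of 34 members did not pass, and 13 passed adjusted over the list alone. Nuclear genes of oxidative phosphorylation had a median of -0.12 over 54 members, none called and 0 adjusted over the list alone. Sarcomere genes had a median of 0.17; Actn2, alpha-actinin, rose by 0.46 (adjusted p = 0.0449), and 5 were higher and 1 lower adjusted over the list alone. Interferon response genes had a median of -0.23; Ifit1 fell, and 3 were lower adjusted over the list alone. Unfolded protein and heat shock genes had a median of -0.21, none called, with 5 lower and 1 higher adjusted over the list alone. Tgfb2, a transforming growth factor, rose by 0.82 (adjusted p = 0.0331), the 1 call of 27 TGF-beta and BMP genes and 1 adjusted over the list alone. Ptgds, a prostaglandin D synthase, rose by 0.85 (adjusted p = 0.0372), the 1 call of 24 arachidonic acid genes, of which 5 were higher and 4 lower adjusted over the list alone.

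Camera with its preset correlation called 9 of 29 lists in WT_TAC against WT_NS. None of these calls was kept with an estimated correlation. Sarcomere, interferon, fibroblast and activated fibroblast lists had an adjusted p = 0.541, and oxidative phosphorylation and unfolded protein lists an adjusted p = 0.614, with an estimated correlation. The number of called genes fell to 17 without WT_NS 1, 18 without WT_NS 3 and 31 without WT_TAC 3. Of 28 called genes named for this comparison, Nlrc3, Scx, Acot1 and Tmem82 stayed called with each of 6 libraries left out in turn, 24 lost the call without at least 1 of them, and 8 (Des, Actn2, Ech1, Ifit1, Ptgds, Siah2, Slc17a7 and Hlx) lost it without any of them.

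**Figure D1:**
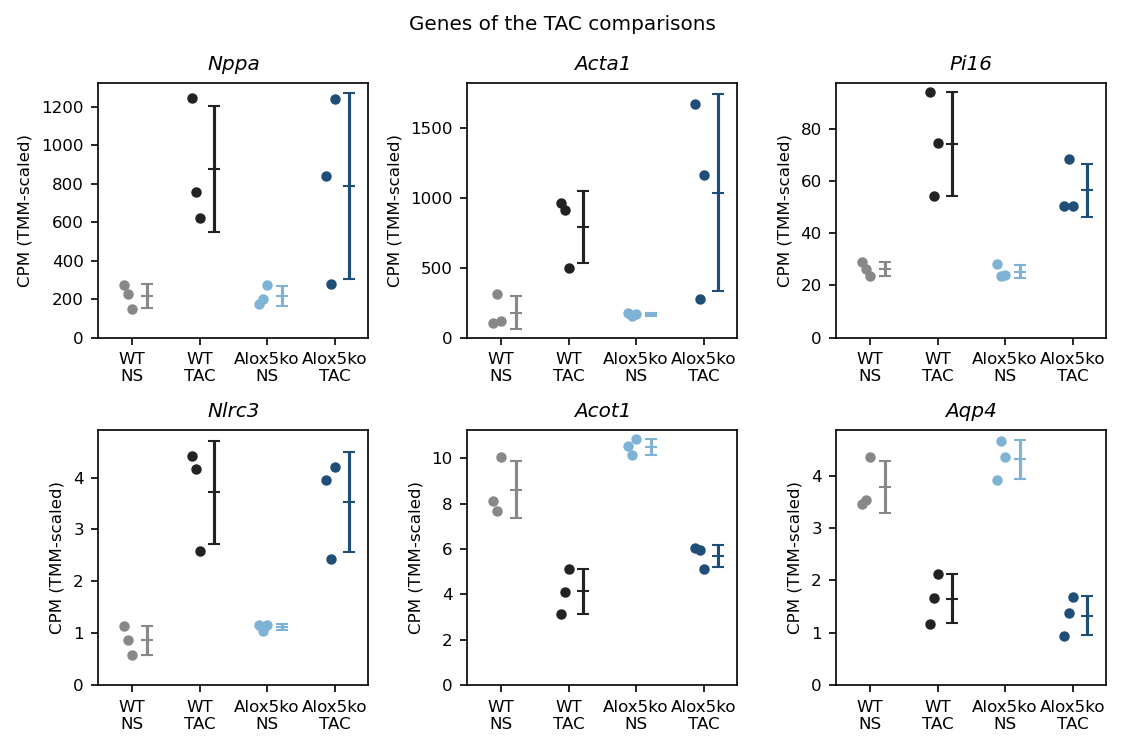
Level of 6 genes in CPM scaled by TMM (y axis) in the 4 groups (x axis); each point is a library, and the bar is the mean with the SD of 3 libraries. Pi16 was 54.2 to 94.1 CPM in WT_TAC and 23.6 to 29.0 CPM in WT_NS, while Nppa and Acta1 in 1 Alox5ko_TAC library, at 278 CPM each, lay far below the other libraries of that group and were singled out after their values were seen.

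The second comparison of TAC asks how the knockout left ventricle responds. In Alox5ko_TAC against Alox5ko_NS, 209 genes changed; 114 rose and 95 fell, 47 of them by at least 2-fold. Nlrc3 rose by 1.65 (SE 0.264, adjusted p = 0.00522), C4b by 1.39, Cnksr1 by 1.41 and Klhl34 by 1.36. Xirp2, a stress-induced protein of the intercalated disc, rose from 708 ± 20.9 to 1684 ± 508 CPM (SD, n = 3). Aqp4 fell by 1.71 (SE 0.224, adjusted p = 0.000972), and Cenpf, Dixdc1, Slc25a33 and the phospholipase gene Pla2g5 fell by 1.47, 1.37, 1.29 and 1.06. Pla2g5 was the 1 call of 24 arachidonic acid genes, with 1 higher and 1 lower adjusted over the list alone.

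All 18 fetal and hypertrophic genes had a positive value in Alox5ko, with a median of 0.94; Xirp2 and Pfkp rose, and 16 passed adjusted over the list alone. Alox5ko_TAC 2 stood apart in this list: the summed level was 18820, 11000 and 18430 CPM in Alox5ko_TAC 1, 2 and 3 against 7092 to 8193 CPM in Alox5ko_NS, and Xirp2 was 1942, 1099 and 2012 CPM. Des did not pass. Extracellular matrix genes had a median of 0.56 over 45 members; 44 did not pass over all genes, and 15 passed adjusted over the list alone. TGF-beta and BMP genes had a median of 0.17: Tgfb2 rose by 1.08 (adjusted p = 0.00452), Inhbb, an activin subunit, by 1.14 (adjusted p = 0.00715) and Gdf6 rose to 26, 15 and 21 counts from 8, 8 and 4 (adjusted p = 0.0337), with 7 higher and 1 lower adjusted over the list alone. Pi16 rose by 1.16 among fibroblast markers (median 0.17, 1 adjusted over the list alone). Activated fibroblast markers had a median of 1.55 over 8 members, none called and 4 adjusted over the list alone; their summed level was 196, 82.2 and 220 CPM in Alox5ko_TAC 1, 2 and 3, with Alox5ko_TAC 2 again apart.

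Acot1 and Acaa2 fell in Alox5ko by 0.88 and 0.38 among 34 fatty acid oxidation genes, whose median was -0.25, with 15 lower adjusted over the list alone. Of 13 mitochondrially encoded genes, which code for respiratory chain subunits, mt-Nd4l, mt-Nd5 and mt-Nd6 fell by 0.44, 0.42 and 0.44; the median was -0.26, with 8 lower adjusted over the list alone. The mitochondrial share of counts was 19.4% ± 1.74 in Alox5ko_NS and 15.9% ± 1.15 in Alox5ko_TAC, against 17.3% ± 0.802 in WT_NS and 16.7% ± 0.832 in WT_TAC (SD, n = 3), with 21.4% in Alox5ko_NS 3. These shares do not include the nuclear gene models that resemble mitochondrial genes. Nuclear oxidative phosphorylation genes had a median of -0.14, none called and 0 adjusted over the list alone. Among 32 calcium and channel genes (median -0.12, 5 lower adjusted over the list alone) the potassium channel gene Kcnd2 fell by 0.69. Clock genes went both ways: Nfil3 rose by 0.65 and Nr1d2 fell by 0.96, with 3 higher and 3 lower adjusted over the list alone. Unfolded protein genes had a median of 0.29, none called, and 11 were higher adjusted over the list alone.

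Camera called 16 lists in Alox5ko_TAC against Alox5ko_NS, and none was kept with an estimated correlation. The fetal, fatty acid oxidation, TGF-beta and activated fibroblast lists had an adjusted p = 0.358 with an estimated correlation. Extracellular matrix, mitochondrially encoded, interferon (median 0.22), unfolded protein and endothelial (median 0.23) lists had an adjusted p = 0.36 with an estimated correlation. The Runx list (median 0.28) and calcium list had an adjusted p = 0.366, the fibroblast list 0.398, oxidative phosphorylation 0.458, immediate early genes (median 0.22) and sarcomere (median 0.18) 0.529, and macrophages (median 0.16) 0.566, each an adjusted p with an estimated correlation. Fry gave fatty acid oxidation an adjusted p = 0.0394. The count of called genes was 379 without Alox5ko_TAC 2, 72, 69 and 93 without Alox5ko_NS 1, 2 and 3, and 60 and 64 without Alox5ko_TAC 1 and 3. Of 23 called genes named here, Nlrc3, Aqp4, Acot1, Tgfb2, Inhbb, Nfil3 and Nr1d2 stayed called with each of 6 libraries left out in turn, while 15 others lost the call without 1 to 5 of them and Cenpf without any of the 6.

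The TAC responses of the genotypes shared 36 genes called in the same direction, 24 higher and 12 lower, where 0.818 would be shared by chance if genes were independent; none was called in opposite directions. Both tests take the spread of a gene from all 12 libraries, so the chance value may be too low. In fits of only the 6 libraries compared, 26 genes were shared in the same direction. The TAC comparisons of the genotypes share no library. Nlrc3, Pi16, C4b, Cnksr1 and Tgfb2 rose in both, and Acot1, Acaa2 and Aqp4 fell in both. Of the 119 genes called in WT, 110 had the same sign in Alox5ko, and of the 209 called in Alox5ko, 195 had the same sign in WT. The count of 36 was 84 without Alox5ko_TAC 2. It was 7 and 6 without WT_NS 1 and 3, 17, 20 and 20 without WT_TAC 1, 2 and 3, 10, 20 and 15 without Alox5ko_NS 1, 2 and 3, and 17 and 12 without Alox5ko_TAC 1 and 3.

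**Figure D2:**
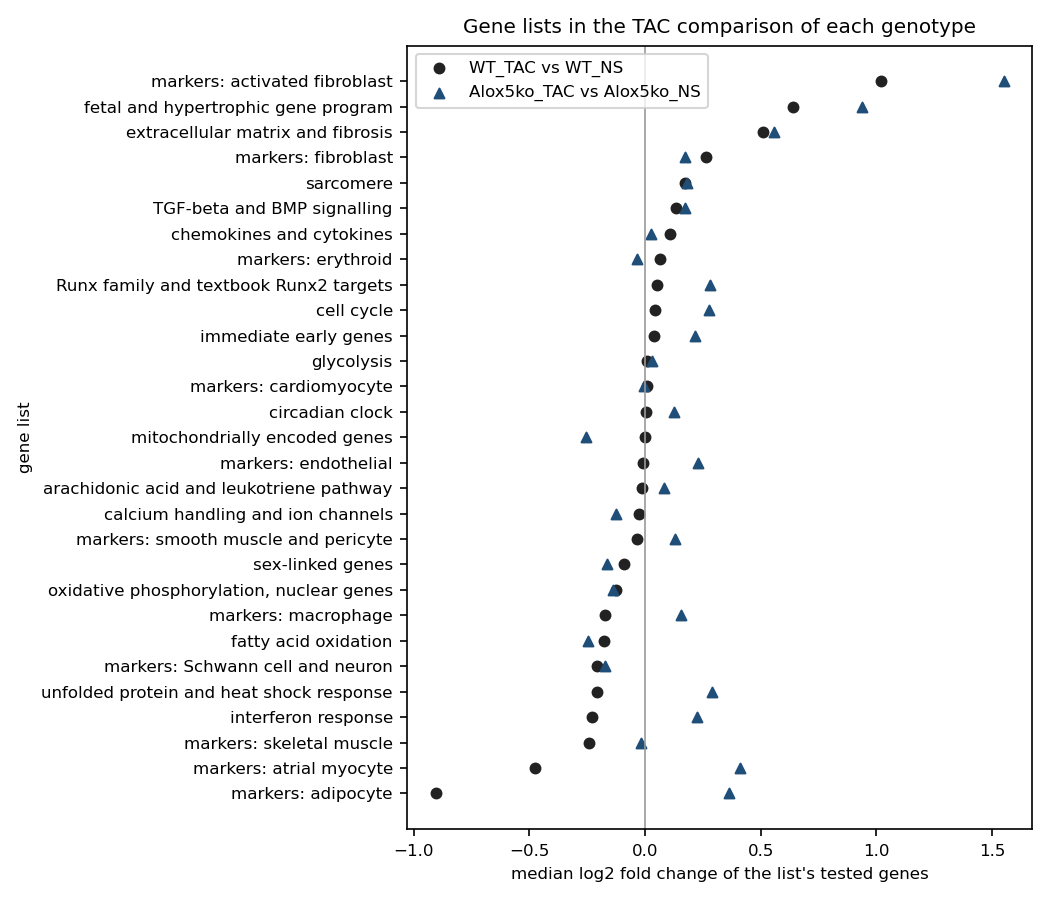
Median log2 fold change of the tested genes of each of 29 lists (x axis) for each list (y axis), with circles for WT_TAC vs WT_NS and triangles for Alox5ko_TAC vs Alox5ko_NS. Activated fibroblast markers had the highest median in both genotypes (1.02 and 1.55), and the interferon list had medians of -0.23 and 0.22.

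The next comparison asks what the Alox5 genotype changes under TAC. In Alox5ko_TAC against WT_TAC, 17 genes changed; 12 rose and 5 fell. Besides Alox5, the signalling gene Wnt5b fell by 1.32 (SE 0.201, adjusted p = 0.00489), the receptor tyrosine kinase gene Ret by 1.28 (SE 0.223, adjusted p = 0.0188), the homeobox gene Hlx by 0.86 (adjusted p = 0.0437) and the calcium channel gene Itpr1 by 0.51 (adjusted p = 0.0475). Thrsp, a regulator of lipid synthesis, rose by 0.83 (SE 0.133, adjusted p = 0.00929), from 12.9 ± 1.25 to 23.0 ± 2.89 CPM (SD, n = 3). The insulin-degrading enzyme gene Ide rose by 0.81 (SE 0.128, adjusted p = 0.00969), and Nnt, a mitochondrial transhydrogenase, by 0.54 (SE 0.103, adjusted p = 0.0489).

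The 9 other rises fell outside the naming rule and were named after their values were seen: Shisa6 at 1.55 (adjusted p = 0.0299) and 8 genes or gene models of the Hist2 histone cluster on chromosome 3. Hist2h2ab had 56, 47 and 56 counts in Alox5ko_TAC and at most 3 in each of the other 9 libraries. Hist2h2ac had 31, 28 and 27 counts in Alox5ko_TAC and at most 3 elsewhere. Hist2h2aa1 had 65, 67 and 76 counts in Alox5ko_TAC and 8 to 19 elsewhere. The other 5 were Gm15444, Gm44492, Gm20633, Gm20634 and AC125099.1, whose exons overlap those of these histone genes; with 5 of the 8 left out so that 1 per group of overlapping genes stayed, a choice made after seeing the data, the count was 9, so 3 further calls were lost.

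Of 29 unfolded protein and heat shock genes, 27 had a positive value in Alox5ko_TAC against WT_TAC, with a median of 0.29, none called and 11 higher adjusted over the list alone. Camera's call of the list was lost at an adjusted p = 0.589 with an estimated correlation. The chaperone genes Hsph1, Hsp90b1 and Hspa5 had values of 0.75, 0.30 and 0.29 (adjusted p = 0.265, 0.275 and 0.312). Extracellular matrix genes had a median of -0.35, negative for 44 of 45, none called and 0 adjusted over the list alone (adjusted p = 0.759 with an estimated correlation). Their summed level was 3340, 2487 and 3149 CPM in Alox5ko_TAC, and without WT_TAC 1, at 4948 CPM, the WT_TAC libraries (2681 and 3058 CPM) lay within that range. Immediate early genes had none called and 4 lower adjusted over the list alone, among them Klf2 at -0.59 and Dusp1 at -0.54. Fatty acid oxidation (median 0.10), oxidative phosphorylation (median 0.07), interferon (median 0.16), cell cycle (median -0.28), smooth muscle and pericyte (median -0.32) and macrophage (median 0.17) lists had no member called, and only macrophages had a member, 1, adjusted over the list alone.

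Camera called 8 lists in Alox5ko_TAC against WT_TAC, none of them with an estimated correlation. Smooth muscle had an adjusted p = 0.606, fatty acid oxidation 0.636, interferon 0.659, cell cycle and macrophages 0.759, and oxidative phosphorylation 0.772, each an adjusted p with an estimated correlation. The count of genes was 27 without WT_TAC 1 and 10 without WT_TAC 3 or Alox5ko_TAC 3. Alox5, Hist2h2ab, Hist2h2ac, Hist2h2aa1, Gm15444, Gm20633 and AC125099.1 stayed called with each of 6 libraries left out in turn; Thrsp lost its call without WT_TAC 3, Wnt5b without Alox5ko_TAC 3, Ide without Alox5ko_TAC 2 or 3, Gm44492 without WT_TAC 1, WT_TAC 3 or Alox5ko_TAC 3, Ret, Shisa6 and Gm20634 without 4 of the 6, Nnt without 5, and Hlx and Itpr1 without any of them.

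Hlx and Thrsp were the 2 genes that TAC changed in WT and that differed in the opposite direction between genotypes under TAC. Hlx rose with TAC in WT by 0.73 (SE 0.162, adjusted p = 0.0395), from 5.31 ± 0.597 to 8.84 ± 0.324 CPM, and was 4.87 ± 0.431 CPM in Alox5ko_TAC (SD, n = 3). Thrsp fell with TAC in WT by 0.63 (SE 0.133, adjusted p = 0.0358). Neither was named by the rule in WT_TAC vs WT_NS; both were named there after their values were seen. Independent genes would give 0.0586 such genes. Both comparisons hold the WT_TAC libraries with opposite signs, so noise alone can give opposite calls. In 50 simulations without any effect the mean was 0.04 and the highest 1. Those simulations held no TAC effect, whereas 119 genes were called in WT_TAC vs WT_NS. Of these 119 genes, 24 had the same sign in Alox5ko_TAC vs WT_TAC. Neither 0.0586 nor 0.04 therefore gives the number of opposite calls to be had from shared noise beside a TAC response. Chance was not excluded for Hlx and Thrsp. The count of 2 was 9 without WT_TAC 1, 5 without WT_TAC 2, 1 without Alox5ko_TAC 3 and 0 without WT_TAC 3 or any 1 of the WT_NS libraries. Across all genes the fold changes of the comparisons had r = -0.406 (Spearman -0.422), and the simulations had a mean r of -0.498; genes are not independent replicates.

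The last comparison of groups asks what the genotype changes without TAC. In Alox5ko_NS against WT_NS, 6 genes changed: Nnt and Ide rose and Alox5, Ret, Wnt5b and Itpr1 fell. Nnt rose by 0.86 (SE 0.104, adjusted p = 0.000763), from 165 ± 8.47 to 299 ± 53.7 CPM (SD, n = 3). Ide rose by 0.87 (SE 0.127, adjusted p = 0.0131). Ret fell by 1.14 (SE 0.202, adjusted p = 0.0475), Wnt5b by 1.13 (SE 0.198, adjusted p = 0.0475) and Itpr1 by 0.59 (SE 0.0984, adjusted p = 0.0303). All 6 were also called in the same direction under TAC, in libraries not shared with this comparison. If genes were independent, 0.00283 would be shared by chance. That value may be too low, since both tests take the spread of a gene from all 12 libraries. Itpr1 (108213096 to 108551109), Ret (118151745 to 118197718) and Wnt5b (119432531 to 119544347) lie on chromosome 6 with Alox5, Nnt on chromosome 13 (119335448 to 119408997) and Ide on chromosome 19 (37268743 to 37337852).

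**Figure D3:**
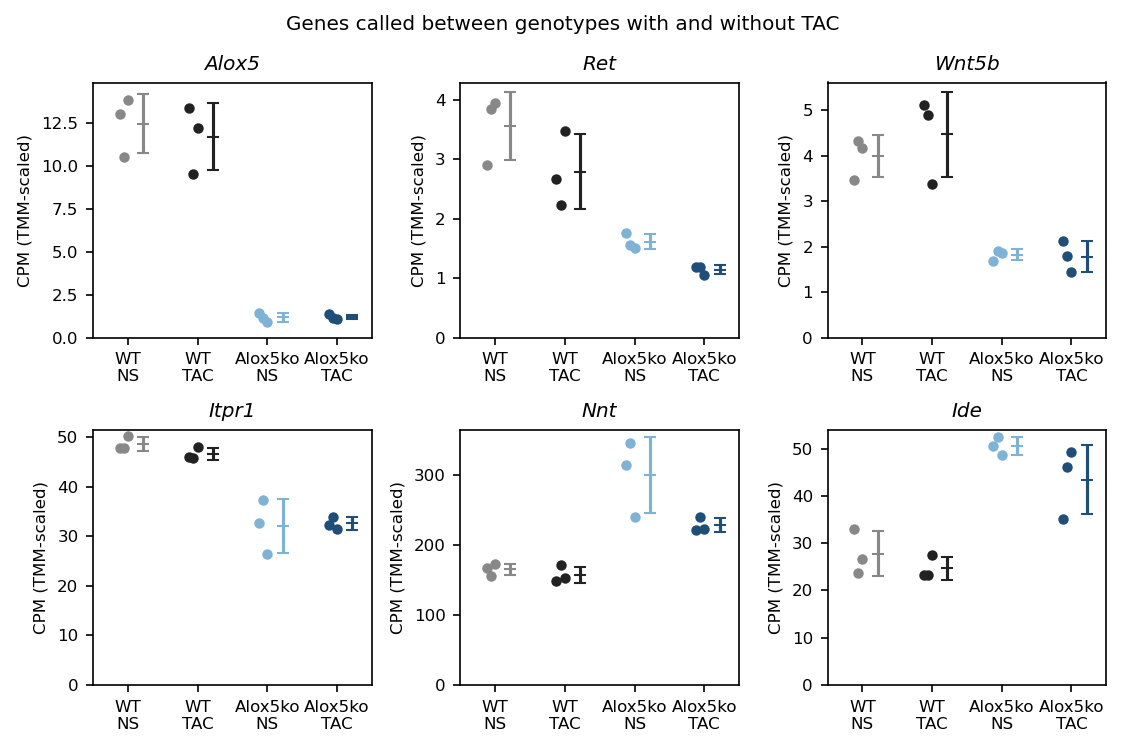
Level of 6 genes in CPM scaled by TMM (y axis) in the 4 groups (x axis); each point is a library, and the bar is the mean with the SD of 3 libraries. Alox5 was at most 1.46 CPM in the 6 knockout libraries and at least 9.56 CPM in the 6 wild-type libraries, and the groups of each gene were apart between genotypes at both treatments.

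All 13 mitochondrially encoded genes had a positive value in Alox5ko_NS against WT_NS, with a median of 0.24, none called and 11 higher adjusted over the list alone. Camera's call of the list was lost at an adjusted p = 0.246 with an estimated correlation. The summed level of these genes was 206800 CPM in Alox5ko_NS 3, which stood apart, against 181000 and 176900 CPM in the other Alox5ko_NS libraries and 159300 to 175400 CPM in WT_NS. Smooth muscle and pericyte markers had a median of -0.37 over 11 members, none called and 4 lower adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). The members with the smallest p-values included Acta2 at -0.88, Cnn1 at -1.41 and Tagln at -0.81 (adjusted p = 0.436, 0.591 and 0.591). Extracellular matrix genes had a median of -0.51 and cell cycle genes of -0.51, with none called and 0 adjusted over the list alone. Interferon genes had a median of -0.31 with 1 lower adjusted over the list alone, and endothelial markers a median of -0.22 with 1 lower adjusted over the list alone. The arachidonic acid list, with Alox5 itself as its 1 call, had a median of -0.12, with 1 higher and 1 lower adjusted over the list alone. Its adjusted p was 0.0331 by fry and 0.198 by camera with an estimated correlation; since the list holds the gene that was knocked out, its tests partly restate the knockout. Fatty acid oxidation (0.13), oxidative phosphorylation (0.09), TGF-beta (-0.16), unfolded protein (-0.10), immediate early (-0.31), activated fibroblast (-0.45) and erythroid (0.40) lists, with their medians, had no member called and 0 adjusted over the list alone.

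Camera called 14 lists in Alox5ko_NS against WT_NS, none of them with an estimated correlation. The interferon list had an adjusted p = 0.198, the endothelial, fatty acid oxidation and TGF-beta lists 0.246, immediate early genes 0.28, extracellular matrix 0.357, cell cycle 0.42, oxidative phosphorylation, activated fibroblasts and erythroid cells 0.609 and the unfolded protein list 0.629, each an adjusted p with an estimated correlation. The count of 6 genes was 2 without WT_NS 2 or Alox5ko_NS 1 and 3 without Alox5ko_NS 3. Of the 6 calls, DESeq2 and the stricter filter each kept 6, RLE scaling 5 and the replicate block 4. The fit without robust estimation and the atrial covariate each kept 3, and limma on log2(RPKM + 1) kept 1. Alox5 and Nnt stayed called with each of 6 libraries left out in turn, Ide, Itpr1 and Ret lost the call without 5 of the 6, and Wnt5b without any of them.

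The interaction asks whether TAC changes a gene differently in the knockout. edgeR called 0 genes, and the smallest adjusted p was 0.509. An unadjusted p under 0.05 was found for 836 of 15542 genes, close to the share of 0.05 that chance alone would give. Hist2h2aa1 (2.41), AC125099.1 (2.52), Rell1 (0.71) and Camk2b (-0.88) were among the genes with the smallest p-values, none of which passed. DESeq2 called 1 gene, Errfi1; limma on log2(RPKM + 1) called 5, all in the Hist2 cluster (Hist2h2ab, Hist2h2ac, Hist2h2aa1, Gm15444 and AC125099.1), and on log2(RPKM + 0.1) called 2 of these, Hist2h2ab and Gm15444. These genes were named after their values were seen. The edgeR count was 1 without WT_TAC 1, WT_TAC 2, Alox5ko_NS 1 or Alox5ko_TAC 3. The fit without a filter called 83, a count that rests on a changed estimate of the spread.

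Interferon response genes had an interaction value above 0 in all 30 tested members, with a median of 0.45, none called and 9 adjusted over the list alone. Usp18, Ifit1 and Irf7, each induced by interferon, had values of 1.21, 0.93 and 0.80 (adjusted p = 0.623, 0.623 and 0.629). Unfolded protein and heat shock genes had a median of 0.39, positive for 27 of 29, none called and 10 adjusted over the list alone. Hsp90b1, Creld2 and Manf had values of 0.48, 0.60 and 0.78 (adjusted p = 0.543 each). Of the clock genes, Per2 had 1.67 and Cry1 0.69 (adjusted p = 0.543 each), with 3 higher and 2 lower adjusted over the list alone. Camera called 6 lists, and the adjusted p with an estimated correlation was 0.183 for interferon, 0.219 for unfolded protein, 0.685 for mitochondrially encoded genes and 0.763 for the calcium, endothelial and macrophage lists.

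Runx2 and Egr1 were named in advance. Runx2, a transcription factor of bone and remodeling tissue, had 2 to 12 counts per library and did not pass the filter. Without a filter its values were 1.27 in WT_TAC vs WT_NS, -0.77 in Alox5ko_TAC vs WT_TAC, 0.997 in Alox5ko_NS vs WT_NS, -0.50 in Alox5ko_TAC vs Alox5ko_NS and -1.77 in the interaction, with unadjusted p-values from the edgeR fit of 0.0542, 0.216, 0.132, 0.424 and 0.0519, none under 0.05 after adjustment; that fit takes its spread mostly from the trend over all genes. The Runx list, with 9 of 20 genes tested, had no member called in any comparison; its median was 0.05 in WT_TAC vs WT_NS, with 3 higher and 2 lower adjusted over the list alone. Egr1, an immediate early transcription factor, had values of 2.005 in WT_TAC vs WT_NS (adjusted p = 0.255), -1.47 in Alox5ko_TAC vs WT_TAC (adjusted p = 0.582), -0.16 in Alox5ko_NS vs WT_NS (adjusted p = 0.981), 0.69 in Alox5ko_TAC vs Alox5ko_NS (adjusted p = 0.702) and -1.32 in the interaction (adjusted p = 0.998). Its level in WT_TAC 2 was 124 CPM, against 9.87 to 35.7 CPM in the other 11 libraries.

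Some libraries stood apart. On the first principal component (21.6% of variance) Alox5ko_TAC 2 was at -1.05 and the other Alox5ko_TAC libraries at 16.6 and 19.96, and WT_TAC 1 was at 30.1 with the other WT_TAC libraries at 12.6 and 12. On the second (13.3%) Alox5ko_NS 3 was at -19.5, with the other Alox5ko_NS libraries at -3.99 and 5.72. The Alox5ko_TAC libraries were at -19.2, -10.2 and -18.9 there, and the WT libraries lay between 3.57 and 16.4. Alox5ko_NS 3 was thus near the Alox5ko_TAC libraries, and the second component mostly parted the genotypes. Alox5ko_NS 2, at 5.72, lay within the range of WT. In a fit of 10 libraries without Alox5ko_NS 3 and Alox5ko_TAC 2, chosen after seeing the data, the counts of called genes in the order WT_TAC vs WT_NS, Alox5ko_TAC vs WT_TAC, Alox5ko_NS vs WT_NS, Alox5ko_TAC vs Alox5ko_NS and interaction were 284, 30, 3, 386 and 0. Of these, 113, 13, 2 and 146 were called in the fit of 12 libraries. Myl4, an atrial myosin light chain, ran from 1.35 to 77.9 CPM, with both ends in knockout libraries, and was picked after its values were seen.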

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

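The tests of variants near Alox5, of a copy number gain, of overlapping exons, of histone RNA and of all interaction lists together, and the count of gene splits for the interaction, were chosen after the result was seen; the other tests in this part were set before.

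The interaction was singled out for 6 lists that camera called with its preset correlation, none of which was called with an estimated correlation. The list medians were 0.449 for the interferon response, 0.393 for the unfolded protein and heat shock response, -0.233 for mitochondrially encoded genes, -0.126 for calcium handling and ion channels, 0.175 for endothelial markers and 0.247 for macrophage markers. No gene of any list passed the interaction test over all genes.

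The first pattern is the positive interaction of interferon and unfolded protein genes: TAC gave medians of -0.23 and -0.21 in WT and 0.22 and 0.29 in Alox5ko. No single library made it, since the smallest median with 1 library left out was 0.383 for interferon (without WT_TAC 3) and 0.267 for unfolded protein genes (without Alox5ko_NS 2). Taken alone, 2 of 100 permutations of genotype within treatment gave an interferon median as far from 0 (highest other 0.555) and 3 of 100 an unfolded protein median as far (highest other 0.452). These lists stood out among 29, however, and in 39 of 100 permutations the most extreme list was as extreme as here, so chance was not excluded. Between genotypes the interferon median was -0.305 without TAC (Alox5ko_NS vs WT_NS) and 0.156 under TAC (Alox5ko_TAC vs WT_TAC). The unfolded protein median was -0.101 without TAC and 0.294 under TAC. The interferon median was thus further from 0 without TAC, where it was negative, but whether the interaction lay more in the groups without TAC was not tested. A different TAC response of the knockout, or a different level without TAC, stays open beside chance, and no other biological explanation was tested.

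The second pattern is the set of 6 genes called between genotypes both with and without TAC, of which Alox5, Itpr1, Ret and Wnt5b lie on chromosome 6. Of 252 uncalled genes within 20 Mb of Alox5, 8 (3.17%) had an unadjusted p under 0.05 and the same sign in both comparisons. In 167 windows on other chromosomes the median was 0.81% and the highest value 3.09%. These windows overlap one another, so they are not 167 separate comparisons. The highest, with 5 of 162 genes, lay on chromosome 13, which also holds Nnt. Variants linked to Alox5 in the knockout line are thus a candidate explanation for the genes near it. Ide on chromosome 19 was called, and Fgfbp3 and Btaf1 nearby had values of 1.05 and 1.21 under TAC without passing (both named after their values were seen), but a gene between Fgfbp3 and Ide had 0.0613 (SE 0.0882), which argues against 1 gain of the whole segment; separate gains were not tested. The mouse strain is not in the labels, and Nnt is known to carry a deletion in the strain C57BL/6J, so a strain difference stays open and untested. An effect of the loss of Alox5 itself on these 5 other genes stays open too. Any linked variant or strain difference would coincide with the knockout in these groups, so the design cannot separate them.

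The third pattern is the 8 genes and gene models of the Hist2 cluster called only in the 2 comparisons that hold Alox5ko_TAC. Their exons overlap in 3 groups, so the 8 calls may rest on as few as 3 signals counted more than once. Genes on opposite strands within a group had nearly the same counts in Alox5ko_TAC 1, 2 and 3. Hist2h2ac had 31, 28 and 27 and Gm44492 30, 28 and 27. Hist2h2ab had 56, 47 and 56 and Gm15444 52, 46 and 56. Hist2h2aa1 had 65, 67 and 76 and AC125099.1 62, 64 and 75. These values argue against 8 separate signals. A rise of histone RNA without a poly(A) tail would lift other histone genes, but 12 other tested histone cluster genes had a median of 0.115 under TAC between genotypes (bootstrap SE 0.103, from -0.21 to 0.449). The counts of Hist2h2ab were 56, 47 and 56 in the 3 Alox5ko_TAC libraries and at most 3 in each of the other 9, so no single library made the pattern. What sets this locus apart in Alox5ko_TAC was not tested and stays open.

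Other splits of the samples were counted for each number of calls. For WT_TAC vs WT_NS, Alox5ko_TAC vs WT_TAC, Alox5ko_NS vs WT_NS and Alox5ko_TAC vs Alox5ko_NS there are 10 splits, too few for a share under 0.05. The real split called 119, 17, 6 and 209 genes, and the highest other split called 0, 8, 0 and 0, so 1 split of 10 reached the real count each time. For the lists called by camera the real splits gave 9, 8, 14 and 16, the highest others 13, 15, 15 and 14, and 5, 8, 2 and 1 splits reached the real count. For the interaction the real count was 0 genes, so all 100 permutations reached it by construction and this count decides nothing. The highest other permutation called 19 genes. The real count of 6 lists was reached by 80 of 100, with the highest other at 20. Every other split called at least 1 list by camera with the preset correlation, so those calls carry little weight here.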

How the results depend on the processing

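The covariate for atrial RNA, the fit of 10 libraries, the fit of nuclear genes alone and the fit with 1 gene per group of overlapping genes were chosen after the data were seen; the other alternatives were set before. Counts are given in the order WT_TAC vs WT_NS, Alox5ko_TAC vs WT_TAC, Alox5ko_NS vs WT_NS, Alox5ko_TAC vs Alox5ko_NS and interaction, which were 119, 17, 6, 209 and 0, then for genes called in opposite directions (2) and in the same direction (36). RLE scaling gave 122, 18, 5, 208, 0, 3 and 37, the stricter filter 117, 16, 6, 212, 0, 2 and 36, and nuclear genes alone 121, 18, 6, 206, 0, 3 and 37. The replicate block gave 110, 21, 6, 170, 0, 6 and 27, and kept 85 of the 119 calls in WT_TAC vs WT_NS. No pair of libraries with the same number had a correlation above 0.1 (-0.121 to 0.0916), and 5 of 12 libraries correlated best with their own number. These values gave no clear sign that the numbers pair the samples, but pairing was not excluded. Pairs with the same number had 0.0732, 0.0916 and 0.0440 between WT_NS and WT_TAC, and -0.105, 0.0813 and 0.0570 between Alox5ko_NS and Alox5ko_TAC. Without robust estimation the counts were 131, 16, 3, 212, 0, 1 and 44. Only the 6 libraries compared gave 215, 39, 18 and 159, then 9 and 26; this fit cannot give an interaction. DESeq2 gave 288, 55, 23, 401, 1, 15 and 111, and shared 117, 17, 6 and 200 calls with edgeR. Limma on log2(RPKM + 1) gave 27, 9, 1, 40, 5, 0 and 7, and on log2(RPKM + 0.1) 24, 8, 2, 47, 2, 0 and 8. A fold of at least 2 gave 33, 12, 3, 47, 0, 0 and 9, by its construction. The atrial covariate gave 185, 19, 3, 137, 0, 3 and 33, the fit of 10 libraries 284, 30, 3, 386, 0, 6 and 95, and 1 gene per group of overlapping genes of the Hist2 cluster 119, 9, 6, 199, 0, 1 and 36; of the 8 calls lost from 17, 5 were of genes left out by its construction. Leaving out 1 library gave 17 to 95, 10 to 27, 2 to 7, 60 to 379, 0 to 1, 0 to 9 and 6 to 84, with fewer samples by construction; WT_TAC 3 and Alox5ko_TAC 3 gave the 10, and Alox5ko_TAC 2 the 379 and the 84. For the other counts that moved, the cause was not tested. Without a filter the counts were 538, 252, 116, 756, 83, 85 and 207. There the prior degrees of freedom became infinite for 24621 of 28070 genes (87.7%), so the spread of a gene came from the trend; 527, 247, 116, 743 and 83 of these calls were of genes that pass the filter, so they are not further findings. Scaling by RLE, by DESeq2 or by nuclear genes alone moved the median of all genes by less than 0.01.

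Of 145 list tests, camera called 53 with the preset correlation, 0 with an estimated one, 2 with fry, 56 with the replicate block and 55 without a filter. For lists, 457 values under alternatives stayed on their side of the threshold, 107 lost and 8 gained a call, and 8 reversed, none of them a call. These were the fetal program in Alox5ko_NS vs WT_NS with fry (0.989), the cell cycle in WT_TAC vs WT_NS with the replicate block (0.943), and without a filter chemokines and cytokines in WT_TAC vs WT_NS (0.654), Alox5ko_TAC vs Alox5ko_NS (0.941) and the interaction (0.664), Schwann cell and neuron markers in WT_TAC vs WT_NS (0.742), the Runx list in Alox5ko_TAC vs WT_TAC (0.632) and skeletal muscle markers in Alox5ko_NS vs WT_NS (0.456), all adjusted p-values.

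For named genes, 2088 values stayed on their side of the threshold, 402 lost and 80 gained a call, and 12 reversed, none of them a call. The log2 fold change of Alox5 in WT_TAC vs WT_NS ran from -0.201 (without WT_NS 2) to 0.0321 (without WT_TAC 2). In Alox5ko_TAC vs Alox5ko_NS that of Alox5 ran from -0.0971 without Alox5ko_NS 3 to 0.22 without Alox5ko_NS 1, and was -0.00991 without Alox5ko_NS 2, -0.0733 without Alox5ko_TAC 1 and -0.0611 with 10 libraries. In the interaction that of Alox5 ran from -0.00418 without Alox5ko_NS 3 to 0.313 without Alox5ko_NS 1, and was -0.00402 without WT_TAC 2. Egr1 in Alox5ko_NS vs WT_NS ran from -0.567 without Alox5ko_NS 3 to 0.348 without WT_NS 2, and was 0.0338 without Alox5ko_NS 1. Cpeb3, between Btaf1 and Ide and named after its values were seen, ran from -0.178 without Alox5ko_TAC 2 to 0.0454 without Alox5ko_TAC 1 in Alox5ko_TAC vs WT_TAC and was 0.0306 without WT_TAC 2, and -0.0325 with the atrial covariate in Alox5ko_NS vs WT_NS. The cause was not tested. At this depth genes with few counts, such as Runx2 with 2 to 12 per library, did not pass the filter.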

Other observations

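No test of an explanation is reported in this part, and the values were picked after the data were seen. Atrial RNA differed between libraries of the same group: Myl4 was 60.2, 14.3 and 23.8 CPM in WT_NS, 50.8, 6.05 and 15.6 CPM in WT_TAC, 1.35, 1.49 and 29.1 CPM in Alox5ko_NS and 7.98, 1.65 and 77.9 CPM in Alox5ko_TAC. The atrial myocyte list had no member called, 0 adjusted over the list alone, and medians of -0.48 in WT_TAC vs WT_NS, -0.08 in Alox5ko_TAC vs WT_TAC, -0.69 in Alox5ko_NS vs WT_NS and 0.41 in Alox5ko_TAC vs Alox5ko_NS. Nppa, which atrial tissue also makes, was 841, 278 and 1239 CPM in Alox5ko_TAC, and Acta1, skeletal alpha-actin, was 1668, 278 and 1161 CPM there, both named after their values were seen. Acta1 had values of 2.15 in WT_TAC vs WT_NS (adjusted p = 0.243) and 2.64 in Alox5ko_TAC vs Alox5ko_NS (adjusted p = 0.127).

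Some lists were called by camera in none of the 5 tests. In WT_TAC vs WT_NS their medians, with the adjusted p of camera at its preset correlation, were 0.01 for glycolysis (0.793), 0.11 for chemokines and cytokines (0.936), 0.00 for the circadian clock (0.793), -0.09 for sex-linked genes (0.793), 0.01 for cardiomyocyte markers (0.936), -0.90 for adipocyte markers (0.234), -0.24 for skeletal muscle markers (0.793) and -0.21 for Schwann cell and neuron markers (0.843). Pfkp, called in Alox5ko_TAC vs Alox5ko_NS, is the 1 call among glycolysis genes there. Neutrophil and B cell markers had 2 tested genes each, T cell and epicardial markers 1 each and lung markers 0, so these lists were not tested by camera; none of their genes was called, and their medians in WT_TAC vs WT_NS were -0.96, 0.16, -0.10 and -0.69 in that order.

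No list called by camera had a median, a mean and a test of different sign. Among lists not called, these differed in sign for the arachidonic acid, immediate early, chemokine, clock, endothelial, smooth muscle and skeletal muscle lists in WT_TAC vs WT_NS, and for the arachidonic acid, Runx, sarcomere, sex-linked, cardiomyocyte and atrial lists in Alox5ko_TAC vs WT_TAC. They also differed for the fetal and sex-linked lists in Alox5ko_NS vs WT_NS, for the chemokine, sex-linked, atrial and skeletal muscle lists in Alox5ko_TAC vs Alox5ko_NS, and for the fatty acid oxidation, chemokine, sex-linked and Schwann cell lists in the interaction.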
